A study of Arabidopsis thaliana with 7 samples.

How the data were processed

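RNA of isolated 8-cell Arabidopsis thaliana embryos was measured on 7 arrays, 4 of wild type (Col-0) and 3 of bdl (IAA12) mutants in the same ecotype. Per the labels' protocols, ovules were collected from siliques, embryos were picked with a micromanipulator, and total RNA was converted to whole-transcript cDNA and labelled with biotin. The authors deposited 1 table with a column of intensity values per array and a row per probe set. RMA is named in the submitters' processing notes, without version. The chip definition and genome build are not given in the sources used here. The values ran on a linear scale with no value at or below 0, and they look like antilogs of RMA values, which no source states. The design, fixed before the data were examined, assumed log2 values and provided for linear ones, so log2 was taken first, with no pseudocount and no further scaling. Scanner files and detection calls were not used here, so the level of background is unknown.

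Each of the 27826 probe sets carries the identifier of 1 locus, so choosing among several probe sets of a gene was not needed. Of these, 176 were identical on all arrays to another probe set, and 6 of them were called. Names came from a RefSeq gene table of assembly TAIR10.1. It held 27241 of the loci, of which 10556 have a symbol of their own, and 585 were not in it. Genes without a symbol are named by locus, and a name from a gene list is used where the table gives it as symbol or synonym. The table served only for names and neighbours.

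Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust, 2-sided), with genotype as the only term and Benjamini-Hochberg adjustment over all 27826 genes. A gene was called at an adjusted p under 0.05. The median SE of a log2 difference was 0.27. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 19 lists, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. With an estimated correlation the calls of the MONOPTEROS target, Aux/IAA and embryo patterning lists held, and those of the SOSEKI, cell wall, early response and ARF lists did not. The 19 lists were written from general knowledge before the data were examined. The IQD list holds the whole family, and the labels do not say whether the study chose IQD6 from these arrays. Position was tested with Fisher's exact test over nuclear loci.

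Genes were named by a rule set before the data were examined. IAA12 came first. Then came the 12 genes per direction with the greatest log2 difference among called genes whose arrays do not overlap. From each list came up to 4 called members with the smallest p, or the 2 with the smallest p where none was called. A further member is named where a count was 5 or fewer, and such names were chosen after their values were seen. Results for some genes that the rule takes are not reported here. Lists for pollen, clock, leaf polarity and NPY genes were added after the data were examined.

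The procedure was tested on simulated data with the real means and spreads of the 27826 genes and 200 changed genes in each of 10 runs. It recovered 16.2% of genes changed by 1 on the log2 scale, 64.0% of those changed by 2 and 84.8% of those changed by 3, and 3.92% of calls were false. Alternatives were other scalings, filters on dim genes at the 25th and 50th percentile, another variance model, array weights, the replicate number as a block, other thresholds and windows, and leaving out each array. Alternatives added after the data were examined were the 4 arrays with the least pollen RNA, the pollen list mean as a covariate, and identical probe sets counted once. Figures were drawn with matplotlib 3.10.9.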

Results

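Transcript levels were measured on 7 one-colour expression arrays, each hybridised with RNA from about 40 to 50 isolated Arabidopsis thaliana embryos of the 8-cell stage. There were 4 arrays of wild-type Col-0 embryos and 3 arrays of embryos mutant for BODENLOS (bdl). BODENLOS is IAA12, an Aux/IAA protein that represses the auxin response factor MONOPTEROS (ARF5). The title of the series concerns the control of oriented cell division in the embryo, and the comparison of genotypes asks which transcripts differ when the auxin response is altered by bdl. The design text speaks of 3 replicates per genotype, but 4 wild-type arrays are labelled, and all were used. The array held 27826 probe sets, each named after 1 locus. The median intensity of an array lay between 8.44 and 9.37. The number of arrays limits the precision, and where the labels do not say that replicates came from separate harvests, p-values measure only the spread between these samples.

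IAA12 itself was higher in bdl. Its intensity was 135 to 167 in the wild-type arrays and 432 to 477 in the bdl arrays, a log2 difference of 1.59 ± 0.17 (SE; 4 against 3 arrays; limma, adjusted p = 0.00287). The labels do not say how the mutant protein is expressed, and an altered protein sequence need not change the transcript level. The growth protocol mentions selection of transgenic seeds without saying whether these embryos carried a transgene, and the signal does not tell the native locus from an added copy. The level of IAA12 therefore does not by itself check the genotype.

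In bdl embryos 490 of the 27826 genes changed, 251 higher and 239 lower, and 480 of them differed at least 2-fold. The median log2 difference was 2.01 among the genes that rose, -2.23 among those that fell and -0.01 over all genes. The arrays of the genotypes did not overlap for any of the 490, which is no separate support, since the calls came from the same arrays. Of all tested genes 11.2% were separated, where chance separates 5.71%. BEN1, a reductase-like gene linked to brassinosteroid inactivation, had the greatest difference: its geometric mean intensity was 824 in wild type and 4.57 in bdl, a log2 difference of -7.49 ± 0.18 (SE; adjusted p = 3.08e-06). AGF2, an AT-hook DNA-binding protein, fell by 5.91 on the log2 scale, ZPR4, a little zipper protein gene, by 5.66, RGF8, a peptide hormone gene of the root meristem growth factor family, by 5.30, and NPY5, an NPH3-family gene of the PINOID pathway, by 5.18. The other genes of the 12 that fell most were AT3G15680, AT1G71691, AT1G04880, AT4G31760, AT4G29030, AT3G08030 and IAA30, with log2 differences of -6.06 to -4.87. Among those that rose, AT1G33750 had the greatest difference, 5.97 ± 0.27 (SE; adjusted p = 4.82e-05), followed by ARAB-1 at 5.78 and its neighbour in locus order AT1G28660 at 5.73. AT1G26680, DPA4 (a repressor of CUC genes), NIMIN1 (an interactor of NPR1), AT5G11930, AT1G66110, AT1G49470, AT1G34047, CP1 (a cysteine proteinase) and AT2G16660 rose by 5.59 to 4.47. AT1G34047 lost its call when any of 5 arrays (wild type 2 or 3, or bdl 1, 2 or 3) was left out, with log2 differences of 4.11 to 5.32 over the 7 omissions. The count of calls fell to 281, 278 and 299 without bdl replicate 1, 2 and 3, and to 105 on the 4 arrays with the least pollen transcripts, a setting added after the data were examined. There 21 of 50 named calls were lost, that of IAA12 among them (log2 difference 1.54; limma, adjusted p = 0.164), with fewer arrays. No detection calls were used here, so levels on the weak side of a fold, which in 35 of the 490 genes lay under the 25th percentile of all intensities, are not known to exceed background.

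**Figure D1:**
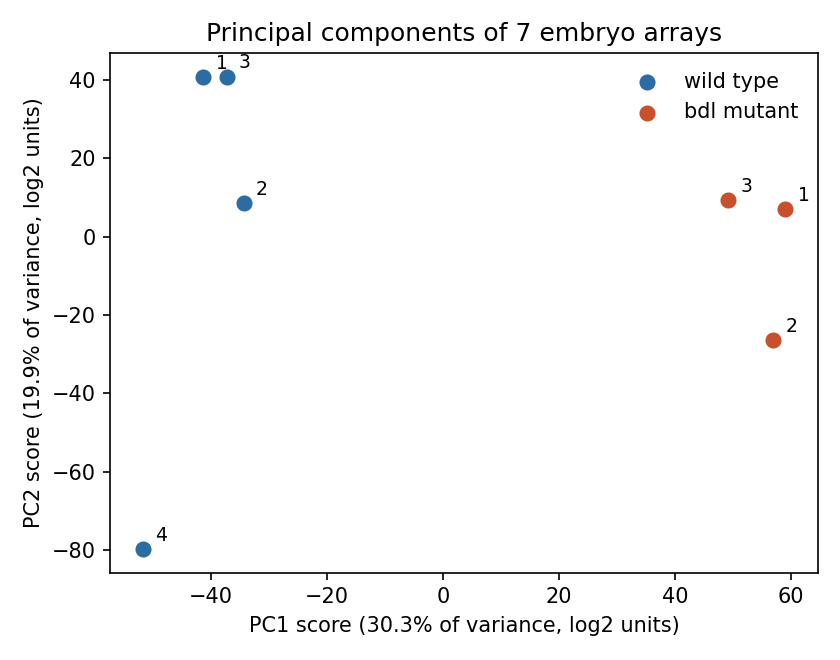
Scores of the 7 arrays on the first principal components of log2 intensity, PC1 on the horizontal and PC2 on the vertical axis, with each point an array labelled by its replicate number and coloured by genotype. PC1 (30.3% of the variance) runs from -51.8 to -34.4 in wild type and from 49.1 to 59.0 in bdl, and wild type replicate 4 lies at -79.7 on PC2 (19.9%).

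Known targets of MONOPTEROS fell together in bdl. Of 22 measured members of this list, 10 fell, 1 rose and 11 did not pass the test, and the median log2 difference was -1.50 (camera, adjusted p = 1.36e-12 over 19 lists; adjusted p = 0.00739 with an estimated correlation). IAA30 fell by 4.87 and the vascular bHLH genes TMO5 and T5L1 by 3.24 and 3.19. The member that rose was FIL, a YABBY gene of abaxial identity, at 1.43. The Aux/IAA family also fell as a group: 8 of 29 members were lower, 1 was higher (IAA12) and 20 did not pass, with a median of -0.45 (camera, adjusted p = 1.38e-09; adjusted p = 0.00739 with an estimated correlation). IAA1 fell by 4.17, IAA2 by 2.31 and IAA9 by 2.12 on the log2 scale. Adjusted over the list alone, 13 MONOPTEROS targets and 12 Aux/IAA genes passed. Some members that did not pass lay under the 25th percentile of log2 intensity (1.81) in both genotypes, where a fall could be missed. Examples are IAA5 (1.64 in wild type and 1.56 in bdl) and TMO7 (1.38 and 1.53). Others, such as IAA11 (4.72 and 4.32), were better expressed. IAA30 and IAA20 stand in both the MONOPTEROS target and the Aux/IAA list. The MONOPTEROS target list also shares members with other lists, so the lists are not independent. ARR7, which fell, and ARR15 also stand in the cytokinin response list.

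**Figure D2:**
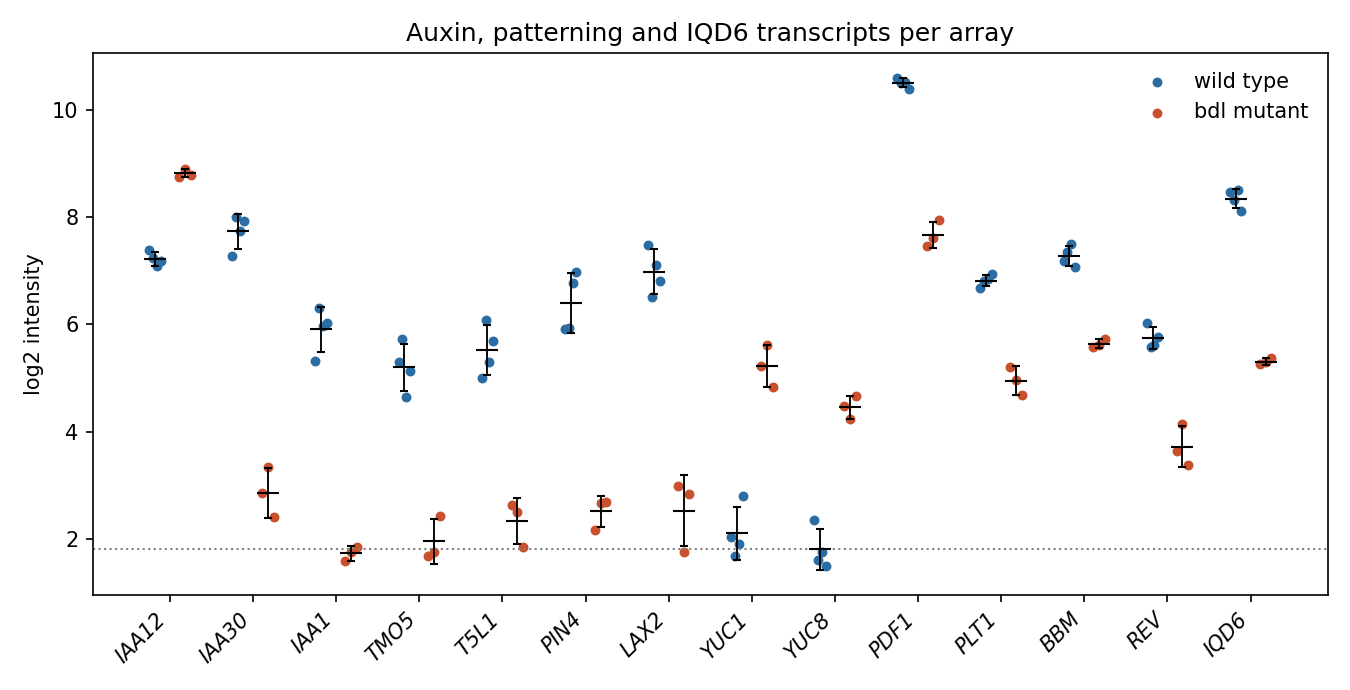
Log2 intensity (vertical axis) of 14 named genes on each array, wild type and bdl side by side; points are arrays, the horizontal bar with its error bar is the mean ± SD, and the dotted line is the 25th percentile of all values (1.81). IAA12, YUC1 and YUC8 lie higher in every bdl array than in any wild-type array and the other 11 genes lie lower.

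The called genes of auxin transport and synthesis went both ways. Of 27 members, 3 fell, 3 rose and 21 did not pass, and the list as a whole did not pass (camera, adjusted p = 0.503). The influx carrier LAX2 fell by 4.45 and the efflux carrier PIN4 by 3.88, while the auxin biosynthesis genes YUC1 and YUC8 rose by 3.12 and 2.65 and YUC4 by 2.33. With p adjusted over the list alone, 11 passed. Of 21 early auxin-response genes (GH3, SAUR and LBD genes among them), HB2, a homeodomain gene, fell by 2.86, and the other 20 did not pass. Some of those 20 lay under the 25th percentile of log2 intensity (1.81) in both genotypes, where a fall could be missed. SAUR22 (1.01 in wild type and 0.98 in bdl) and GH3.17 (1.46 and 1.46) are examples, while LBD18 (4.48 and 4.86) was better expressed. The lack of a call does not show that the dim members of this list were unchanged. The median was -0.24 (camera, adjusted p = 0.0195; adjusted p = 0.206 with an estimated correlation), and without wild type 4 or bdl 3 the list's adjusted p was 0.118 and 0.0781. Of 15 ARF genes only ARF3 passed, at -1.46 (adjusted p = 0.0438), and it passed in none of the 7 omissions of an array (-1.63 to -1.19). The ARF list had a median of -0.27 (camera, adjusted p = 0.0481; adjusted p = 0.166 with an estimated correlation), and its adjusted p rose to between 0.0549 and 0.0906 without wild type 2 or 4 or bdl 1, 2 or 3. ARR7, a cytokinin response regulator, fell by 3.33 and the other 9 members of its list did not pass (camera, adjusted p = 0.503). Adjusted over the list alone, 1 early response gene, 2 ARF genes and 1 cytokinin response gene passed.

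Among 25 embryo patterning genes, 7 fell, 1 rose and 17 did not pass, with a median of -0.29 (camera, adjusted p = 6.21e-07; adjusted p = 0.0123 with an estimated correlation). PDF1, an epidermal protein gene, fell from a geometric mean intensity of 1448 to 204, a log2 difference of -2.83 ± 0.19 (SE; adjusted p = 0.000318). The AP2-type stem cell regulators PLT1 and BBM fell by 1.86 and 1.63, and REV, a class III HD-ZIP gene, by 2.02. The other 3 that fell were PHB, AGO10 and SHR, and CUC2, a boundary gene, rose by 2.92. When adjusted over the list alone, 14 passed. Of 10 seed maturation genes, ABI3 fell by 2.24 and FUS3 rose by 1.02 (adjusted p = 0.0451). FUS3 passed in none of the 7 omissions of an array (0.91 to 1.13). The median of this list was 0.11, its mean -0.02 and its camera direction lower (adjusted p = 0.892), so the signs differ. The count was 3 when adjusted over the list alone.

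**Figure D3:**
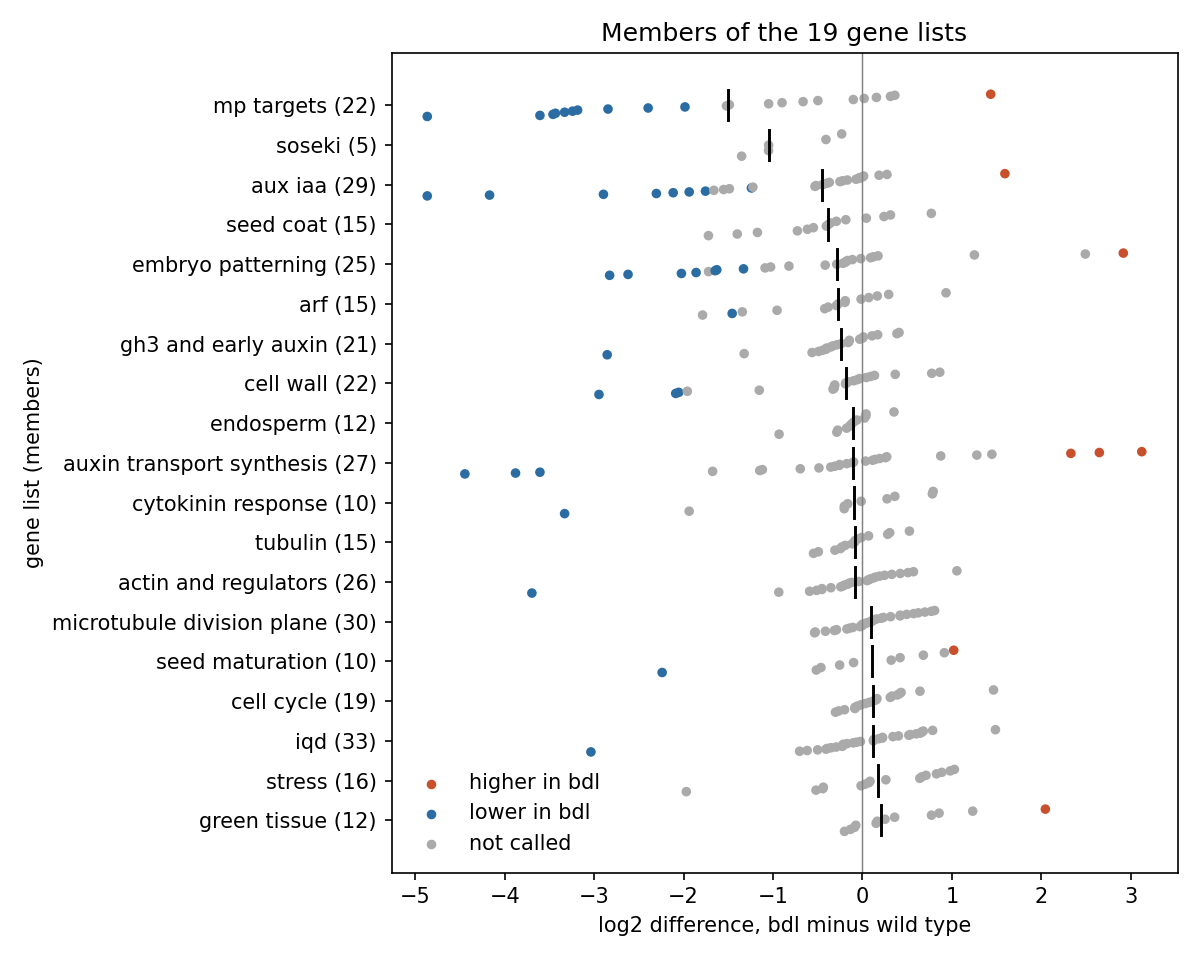
Log2 difference, bdl minus wild type (horizontal axis), of each member of the 19 gene lists (vertical axis, with the number of members); points are genes coloured by their call over all 27826 genes, and the black bar is the list's median. The MONOPTEROS target list has the lowest median, -1.50, and tubulin, division plane, cell cycle, endosperm, SOSEKI, seed coat and stress lists hold no called member.

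In the lists of cytoskeleton and division plane genes most members did not pass, and these lists do not hold every such gene. IQD6, which encodes a calmodulin-binding protein of a family associated with microtubules, fell by 3.04 (SE 0.18; adjusted p = 0.000164), from a geometric mean intensity of 325 to 39.6. The other 32 IQD genes did not pass, and the list's median was 0.12 (camera, adjusted p = 0.503). The list of 26 actin cytoskeleton genes and their regulators did not pass (camera, adjusted p = 0.681); 1 member fell and 25 did not pass. None of 15 tubulin genes, 30 microtubule and division plane genes or 19 cell cycle genes passed by limma over all genes. Their list adjusted p-values were 0.439, 0.185 and 0.129 by camera. By fry, which does not compare a list with other genes, they were 0.0848, 0.0302 and 0.00266. The division plane and cell cycle lists thus passed by fry, toward higher levels in bdl. The smallest p in these lists belonged to TUB7 (-0.49) and TUA1 (-0.55), MAP65-6 (0.81) and MAP65-2 (0.77), and CYCB2;1 (1.47) and CDKB1;2 (0.64). Without wild type 1, CYCB2;1 was called at 1.76 (limma, adjusted p = 0.0151), and it was not called in the other 6 omissions of an array. At an unadjusted p under 0.05 the count was 0 tubulin, 3 division plane and 1 cell cycle gene. Adjusted over the list alone, 1 IQD gene, 1 gene of the actin list and 1 cell cycle gene passed, and no tubulin or division plane gene did. Outside these lists, 3 of 33 genes with the symbol stem TRM were called lower, TRM22, TRM24 and TRM31, where 0.39 would be called by chance. That family did not pass in a test chosen after the data were seen (Fisher's exact test, 1-sided, adjusted p = 0.754). The simulated recovery was 16.2% of genes changed by 1 on the log2 scale and 64.0% of those changed by 2. Its changed genes were drawn from all genes, and recovery in these lists was not simulated. Changes of 1 or less in these lists could thus have been missed.

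The 5 loci entered as SOSEKI, a family of polarly localised proteins, had a median of -1.05 (camera, adjusted p = 0.00442; adjusted p = 0.0938 with an estimated correlation), but none passed by itself by limma over all genes, and 2 had an unadjusted p under 0.05. The smallest p belonged to AT5G10150 (-1.35) and AT3G46110 (-1.05). AT5G10150 was called only when wild type 1 was left out (-1.64; limma, adjusted p = 0.0451). Of 22 cell wall genes, the expansins EXPA15, EXPA6 and EXPA10 fell by 2.06, 2.09 and 2.95, and the median was -0.19 (camera, adjusted p = 0.0134; adjusted p = 0.135 with an estimated correlation). EXPA10 lost its call without wild type 2 or 3 or bdl 1, 2 or 3 (-3.29 to -2.55 over the 7 omissions). Adjusted over the list alone, 1 SOSEKI locus and 4 cell wall genes passed.

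No list of markers of tissues that isolated embryos can carry along passed by camera in the reported setting. Endosperm genes had a median of -0.11 (camera, adjusted p = 0.439) and none of 12 passed, with SUC5 at -0.93 and FIS2 at 0.35. Seed coat genes had a median of -0.38 (adjusted p = 0.1002), the same direction as the auxin response lists, and none of 15 passed; TT1 was at 0.77, but all 8 better expressed markers were lower, from -0.36 to -1.72 (STK). This list passed without wild type 4, bdl 1 or bdl 2 (adjusted p = 0.0482, 0.0154 and 0.0324 by camera with limma) and among genes with a mean above the 50th percentile (0.00992), but without bdl 3 its adjusted p was 0.804. The list mean was 3.66 and 3.52 in bdl 1 and 2, inside the wild-type range of 3.29 to 4.18, and only bdl 3, at 2.56, lay below it. Green tissue genes had a median of 0.21 (adjusted p = 0.0563; 0.0422, 0.0177 and 0.0122 without wild type 2, wild type 3 or bdl 3, and 0.0461 with array medians centred), and LHCB1.3 rose by 2.05, a call lost without wild type 1, 2 or 4 or bdl 1 or 3 (1.78 to 2.36 over the 7 omissions). Stress genes had a median of 0.17 (adjusted p = 0.129) and none of 16 passed, with ZAT12 at 0.89 and HSP101 at 0.71. At an unadjusted p under 0.05 the count was 1 endosperm, 4 seed coat and 4 stress genes. The number that passed when adjusted over the list alone was 3 for seed coat and 1 for green tissue genes, with no endosperm or stress gene.

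No concentration of changed genes around IAA12 was detected. Of 882 genes within 500 genes either side of it in locus order on chromosome 1, 17 were called, an odds ratio of 1.095 against the rest of the nuclear genome (95% interval 0.63 to 1.78; Fisher's exact test, 2-sided, p = 0.696). Within 250 genes the odds ratio was 1.37, with a wider interval of 0.70 to 2.44. Correlations between arrays were 0.934 to 0.960 within a genotype and 0.921 to 0.945 between genotypes, computed across genes, which are not independent replicates.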

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

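The tests of seed coat RNA as the whole cause of the lower genes and of scaling as the whole cause of the pollen excess were chosen after their results were seen, as were the pollen and clock lists, and the bounds of the other tests were set before. In 87 checks of the 4 wild-type arrays (named genes, list means, principal components and organelle medians), 2 values stood apart from the other 3 arrays, where chance alone gives about 1 in 20. RGF8 had a log2 intensity of 8.09 in wild type replicate 3 against 7.63 to 7.70 in the others, and ZAT12 had 3.48 in wild type replicate 4 against 3.05 to 3.11. The 3 bdl arrays are too few for this check.

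The 490 changed genes were weighed first. The real grouping was 1 of 35 splits of the arrays to give as many, a rank that argues against chance. The highest other split gave 11, but all other splits mix the genotypes, which widens the spread within groups and lowers their counts. Only the rank therefore counts. That rank does not exclude chance, since 0.0286 is the smallest p that a permutation test over 35 splits can give. The splits also cannot tell genotype from anything else that differed along with it. A segment of another accession around IAA12 is argued against as the cause of the whole set, since 473 of the 490 lie outside 500 genes either side and the odds ratio there was 1.095, with an interval that ends at 1.78, below the bound of 2; a shorter segment that affects some of the 12 called genes within 250 genes stays open, as the interval there, 0.70 to 2.44, crosses that bound. Uneven pollen RNA as the cause of the whole set is argued against by the pollen list means, which overlapped between genotypes. They were 2.13 to 4.36 in wild type and 1.94 to 3.37 in bdl. With the pollen list mean as a covariate, 100% of the called genes kept their sign and at least 50% of their log2 difference. That adds little, because the genes were picked for a clear genotype difference and the covariate overlapped. With this covariate 412 genes were called, and 376 of the 490 kept their call. The lower quartile of the 8 better expressed seed coat markers, -1.23, lies above the upper quartile of the lower genes, -1.68. This cannot decide whether seed coat RNA accounts for the lower genes, because those were picked for a clear fall and the markers were not. Carried seed tissue stays open. The seed coat median of -0.38 met neither bound while all 8 better expressed markers were lower, and an effect of bdl remains a hypothesis beside it. The shift rests on bdl replicate 3, with a list mean of 2.56 against 3.66 and 3.52 in the other bdl arrays. Those lie inside the wild-type range of 3.29 to 4.18, and without bdl replicate 3 the list's adjusted p was 0.804 (camera).

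Pollen transcripts in wild type replicate 4 were weighed next. Of 18 pollen genes, 17 were higher there than the mean of the other wild-type arrays, with a median excess of 1.57 on the log2 scale; RALF4, a pollen tube peptide gene, was at 6.04 against 1.53 to 1.61 in the other wild-type arrays, and VGD1, a pollen pectin methylesterase gene, was at 8.72 but also at 7.44 in wild type replicate 2 and 7.52 in bdl replicate 2. Scaling as the whole cause is argued against, since cyclic loess left 1.49, or 94.99% of the excess, although the bound of 2 set beforehand could not be reached from 1.57. Pollen RNA carried along is a candidate source, but its excess also stayed under the bound of 2 set for it, so it cannot be told apart from other sources here. The list mean was 4.36 in this array, 3.37 in bdl replicate 2, 3.01 in wild type replicate 2 and 1.94 to 2.21 in the other arrays, and no pollen gene was called between genotypes (limma, 0 of 18 at an unadjusted p under 0.05, smallest adjusted p = 0.676); no biological explanation was tested.

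The clock genes LHY (-1.82), ELF4 (2.46), PRR5 (1.45) and COR27 (2.48) were all called, and sampling at a different time of day could give such a set. Over 14 other clock genes the evening minus morning score was higher in bdl by 0.63, past the bound of 0.5, but with p = 0.229 (exact permutation test, 2-sided, 35 splits). The score was -0.22 ± 0.41 (SD, 4 arrays) in wild type and 0.40 ± 0.67 (SD, 3 arrays) in bdl, but 1.18 in bdl replicate 3 against 0.08 and -0.05 in the other bdl arrays, which lie inside the wild-type range of -0.65 to 0.22. Passing the bound rests on single arrays, as the difference was 0.24 without bdl replicate 3 and 0.48 without wild type replicate 3, and 0.54 to 0.85 when any other array was left out. A shift of time in all bdl arrays is thus not shown, 0.24 is still above the bound of 0.2 that would argue against it, and whether bdl affects clock genes was not tested.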

How the results depend on the processing

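The settings with the 4 arrays of least pollen RNA, the pollen covariate and identical probe sets counted once were chosen after the data were seen. All 490 called genes kept their sign in every refit that tested them. This was fixed in advance for fewer arrays, array weights and the replicate block, since the arrays of the genotypes overlapped for none of the 490. Filters, the other variance model and counting identical probe sets once leave the log2 differences unchanged. Only the other scalings and the pollen covariate could have turned a sign. Of 50 named called genes, 45 kept their call whichever array was left out and 29 under every setting; CYCB2;1 and AT5G10150 gained a call without wild type 1. The calls of the MONOPTEROS target, Aux/IAA and embryo patterning lists held under all 20 alternatives. Leaving out each array gave 278 to 374 changed genes, 132 to 175 higher and 145 to 204 lower. Fewer arrays entered each of these fits, and why the counts fell was not tested. These omissions gave camera list adjusted p-values of 0.0287 to 0.0906 for ARF, 0.00967 to 0.118 for early response and 0.0154 to 0.804 for seed coat genes. They were 0.0122 to 0.213 for green tissue, 0.352 to 0.977 for actin, and 0.754 to 0.977 for seed maturation genes.

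Whether the replicate numbers pair the samples was not settled. Deviations of same-numbered arrays correlated only weakly, at 0.040, 0.036 and 0.047. Among wild type 1 to 3, each bdl array correlated best with its own number. However, wild type 1 correlated better with bdl 3 (0.044) than with bdl 1, and the highest value was wild type 4 with bdl 2 (0.105). With the replicate block, which also sets wild type 4 aside, 188 genes were called, 89 higher and 99 lower. Of the 50 named genes 12 lost their call, IAA12 (1.58, adjusted p = 0.0689 by limma), TMO5, ARF3, PLT1, BBM, REV, EXPA6, LHCB1.3, ABI3, FUS3 and AT1G49470 among them. List adjusted p-values with the block were 0.106 (early response), 0.0694 (ARF) and 0.00855 (seed coat), and 0.740 (actin) and 0.868 (seed maturation) with the direction turned.

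On the 4 arrays with least pollen RNA 105 genes were called, 49 higher and 56 lower, 98 of them among the 490; fewer arrays enter. Of the 50 named genes 21 lost their call, the same 12 and IAA2, IAA9, HB2, T5L1, YUC8, EXPA15, EXPA10, AT1G28660 and AT1G34047; IAA12 was at 1.54 (adjusted p = 0.164). The adjusted p was 0.198 for early response and 0.186 for ARF genes, and 0.965 for both actin and endosperm genes with the direction turned. With the pollen covariate these were 0.0772 (early response), 0.0859 (ARF) and 0.967 (actin, turned). Median centring gave 0.0461 for green tissue. The filter at the 25th percentile gave 0.0562 for ARF and 0.930 for seed maturation (turned), and that at the 50th gave 0.125 for early response, 0.0634 for ARF, 0.00992 for seed coat and 0.827 for seed maturation (turned). An estimated correlation gave 0.206 (early response), 0.166 (ARF), 0.0938 (SOSEKI) and 0.135 (cell wall). By fry the adjusted p was 0.0302 for division plane, 0.00266 for cell cycle and 0.0493 for stress genes, and 0.615 for IQD genes (turned). At an adjusted p under 0.1, 719 genes were called, 383 higher and 336 lower. The odds ratio around IAA12 was 0.938 within 1000 genes. Where no reason is given, the cause was not tested. Counting every probe set by itself equals the reported setting. Signal over background is unknown, which limits the folds of genes dim in either genotype.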

Other observations

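The lists of polarity and NPY genes were written after these genes were seen among the calls, so no test of them counts and their values only describe these arrays. Among 5 class III HD-ZIP genes, which specify adaxial and central identity, REV, CNA and PHB fell, with log2 differences of -2.02, -1.68 and -1.33, while PHV was at 1.25 and HB8 at -0.50 without a call. Among 10 abaxial identity genes, KAN1 rose by 3.38, KAN2 by 2.09 and FIL by 1.43, and ARF3 was lower at -1.46. The list means differed by -0.86 for HD-ZIP III genes and by 0.63 for abaxial genes. Of 5 NPY genes, NPY5, NPY4 and NPY1 fell by 5.18, 3.99 and 2.75, and NPY3 (-0.60) and NPY2 (0.13) did not pass; the list mean differed by -2.48.

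Among 497 families of at least 5 genes with a common symbol stem, tested in both directions (994 Fisher's exact tests, 1-sided, chosen after the data were seen), the IAA family held more lower genes than other genes with a symbol did, 7 of 24 (adjusted p = 8.03e-06). It overlaps the Aux/IAA list. For YUC genes (3 of 11 higher) and AGP genes (4 of 30 lower, AGP5, AGP12, AGP14 and AGP18), the outcome depended on the background: the adjusted p was 0.110 and 0.134 against genes with a symbol, the background that fits the test, and 0.0404 for each against all genes, which was the form computed first. Both results were therefore counted as not passing.

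Called genes lay next to each other in locus order 17 times, against a mean of 8.54 in 10000 shuffles of the calls (permutation p = 0.0064, 1-sided), counting identical probe sets once. The labels give no explanation, and none was tested.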
